A study of Mus musculus with 2 samples.

How the data were processed

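Small RNA was sequenced from the limbs of mouse embryos (Mus musculus, strain B6NCrl) at embryonic day 15.5, per the labels. MicroRNAs (miRNAs) are short RNAs cut from hairpin precursors that repress messenger RNAs by base pairing. Per the labels, total RNA was the starting material, fragments below 30 nt were kept, and both sexes were pooled. The series held 1 group with 2 biological replicates, from pools of 78 embryos (replicate 1) and 62 embryos (replicate 2). No second tissue, stage or treatment was part of the series, so levels were described and the replicates were compared with each other.

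The deposited tables gave whole-number read counts per miRNA gene, not normalized, on the mouse assembly mm10 with the M4 annotation, per the deposited README. Each table had 1973 miRNA genes with Ensembl gene identifiers, 3 count columns and 4 summary lines (unmapped reads, reads with several alignments, reads outside the annotated miRNA genes, and ambiguous reads). The columns had no header. From the values, the first column was the sum of the other 2 for every gene, and the second column held nearly all counts, so these were taken as counts irrespective of strand, sense counts and antisense counts. The aligner, the counter, their versions and any adapter trimming were not given in the sources used here. Reads with several alignments were totalled on their own line and entered no gene. Reads common to near-identical copies of a miRNA are therefore in no count. They are also missing from the library totals, so the share of a gene or list can be too low or too high.

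Gene symbols, positions, host genes and precursor sequences were taken from GENCODE M21 on GRCm38, the same assembly as mm10. By gene identifier 1894 of the 1973 genes matched, and the 79 others held 3 counts in total. A precursor was said to share sequence when it had at least 1 stretch of 20 bases in common with another miRNA gene. A miRNA gene was called exonic or intronic by its overlap with other genes annotated on its own strand. An overlapping exon of any annotated transcript was enough for the exonic call.

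Replicate 1 had 9187400 reads, of which 4263630 (46.4%) were sense counts of miRNA genes. Replicate 2 had 10851823 reads, of which 5151214 (47.5%) were sense counts of miRNA genes. Unmapped reads made up 19.7% and 18.8% of the 2 libraries, and reads outside the annotated miRNA genes on the sense strand 4.54% and 3.99%. These lines entered no library total. Sense counts were divided by the sense total of the library and multiplied by 1000000, a unit abbreviated CPM. A gene with a count of 0 could still have had up to 3 counts, or 0.704 CPM in replicate 1 and 0.582 CPM in replicate 2. Shares of single libraries carry Wilson 95% intervals. Molecular identifiers were not named in the sources used here, so intervals, floors and count tests cover counting error only. Levels are means with the SD over n = 2 replicates.

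A gene was called detected with at least 10 sense counts in both replicates. Agreement was measured across detected genes as Pearson and Spearman correlation of log2(CPM + 1), as the SD of the log2 ratio of CPM, and as the common dispersion from edgeR 4.0.16 in R 4.3.3, given as a biological coefficient of variation. Each detected gene was tested between the libraries with an exact two-sided conditional binomial test given the library totals, followed by Benjamini-Hochberg adjustment and a threshold of 0.05 (scipy 1.17.1, Python 3.11.15). With 1 group no quasi-likelihood test between groups could be made. The binomial test compares 2 libraries against counting noise and says nothing about conditions. Ratios are replicate 2 over replicate 1 throughout.

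There were 15 lists of miRNA genes, namely muscle (myomiRs), cartilage, Hox clusters, mesenchyme and fibroblast, let-7 family, miR-17-92 with its paralogous clusters, the Dlk1-Dio3 imprinted region, epithelium, endothelium, erythroid cells, leukocytes, neurons and glia, liver and gut, pluripotency, and neuroendocrine cells. The median log2 ratio of each list with at least 3 detected members was placed among 10000 random lists of the same size, matched on 5 bins of mean expression. Its percentile describes these libraries and is not a p-value. Genomic clusters were miRNA genes on 1 chromosome and strand with neighbouring starts at most 10 kb apart. The antisense share was taken over all miRNA genes, and per gene with at least 100 counts over both strands in each replicate.

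Named genes are the 15 with the highest mean CPM, and up to 3 of the highest detected members of each list. They also include the 5 with the largest log2 ratio in each direction among genes past the threshold with a mean of at least 100 counts, and the 5 with the highest antisense share, with ties broken by the antisense counts of replicate 1, an order that was not part of the rule as first fixed. Other genes are named where a small count would otherwise be unclear, and were chosen after their values were seen. The lists, the naming rule, the tests and thresholds of the main results and most alternatives were fixed before the data were examined. Most tests of possible technical causes were chosen after the results were seen. The alternatives were counts irrespective of strand, other count minimums, edgeR TMM factors and DESeq2 1.42.0 size factors in place of totals, other denominators, pseudocounts of 0.5 and 10, a threshold of 0.01, cluster distances of 3 and 50 kb, and each replicate alone. A further 3 were chosen after seeing the data, namely a GC correction of the log2 ratios, library totals without the muscle list, and an antisense share without genes that lie opposite another miRNA gene.

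The scripts were tested on simulated counts for the 340 detected genes. With no gene changed, 0% of genes were called. With 200 genes changed 1.2-fold, 66.5% of them were called, and with 200 genes changed 2-fold, 89.5%. In those simulations 25.0% and 69.3% of the unchanged genes were also called, because totals scaled by the library carry a change in composition into every gene. With the shift known, these figures were 3.57% and 0%. Simulated coefficients of variation of 10%, 20% and 40% were recovered as 9.82%, 19.8% and 42.0%. With random log2 ratios, the median of the muscle list of 6 detected genes fell outside the 2.5 to 97.5 percentile range in 9% of 100 draws.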

Results

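MicroRNA-seq profiled the miRNAs of the mouse limb at embryonic day 15.5, a stage at which cartilage models, muscle, vessels and a stratifying epidermis are present together. The limbs were pooled from 78 embryos for replicate 1 and from 62 embryos for replicate 2, with both sexes in each pool. The libraries held 4263630 and 5151214 sense counts over miRNA genes. At least 1 sense count was found for 623 genes in replicate 1 and 630 genes in replicate 2, while 1279 of the 1973 genes had none in either. At least 10 counts in both replicates were found for 340 genes, and at least 100 for 247.

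By counts, the leading miRNA genes of the limb included genes known from epidermis, from cartilage, from the Hox clusters and from the let-7 family. Mir203, which promotes differentiation of epidermal keratinocytes, led with 72531 ± 6726 CPM (SD, n = 2). Mirlet7i, of the let-7 family that accumulates as embryonic cells differentiate, followed with 58918 ± 4504 CPM. Mir140, a miRNA of chondrocytes, stood at 43163 ± 1100.3 CPM, and Mir196b, which represses Hox messenger RNAs, at 40763 ± 6885 CPM. The 10 most abundant genes took 49.3% ± 0.774 of the sense counts and the 50 most abundant 86.5% ± 0.0107 (SD, n = 2). The order of genes leaves out reads with several alignments, 29.4% of the reads of replicate 1 and 29.7% of replicate 2. Families with several copies can therefore rank too low. Ranks are by counted reads, and whether different miRNA sequences were captured equally was not tested.

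On mm10, Mir203 (ENSMUSG00000065574.1) lies on the plus strand of chromosome 12 from 112130880 to 112130955, with no other gene annotated on that strand. It took 6.78% of the sense counts of replicate 1 (Wilson 95% interval 6.75 to 6.80) and 7.73% of replicate 2 (7.71 to 7.75). Mirlet7i (ENSMUSG00000065406.2) lies on the minus strand of chromosome 10 from 122985640 to 122985724, in an exon of the transcribed pseudogene D630033A02Rik. Mir140 (ENSMUSG00000065439.1, chromosome 8, 107551244 to 107551313) overlaps an exon of Wwp2, and Mir196b (ENSMUSG00000065443.1, chromosome 6, 52230081 to 52230165) an exon of Hoxa9. Mir335 (ENSMUSG00000065501.1, chromosome 6, 30741299 to 30741396), from an intron of the paternally expressed gene Mest, had 56127 ± 3514 CPM (SD, n = 2). Mirlet7g, in an intron of Wdr82 on chromosome 9, had 48099 ± 324 CPM.

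Among the other leading genes, Mir23b on chromosome 13 had 53446 ± 2760 CPM and Mir23a on chromosome 8 had 26971 ± 821 CPM. These paralogs share a stretch of 20 bases with another precursor, so reads common to both copies are in neither value. Mir99a, in an intron of Mir99ahg on chromosome 16, had 49851 ± 355 CPM, and Mir322 on chromosome X, whose cluster slows the cell cycle of differentiating myoblasts, had 43119 ± 627 CPM. Mir26b, in an intron of the phosphatase gene Ctdsp1, had 23799 ± 1491 CPM. Mir126a, within the endothelial gene Egfl7 and the overlapping Gm20532, had 22336 ± 903 CPM. Mir214, in an exon of the skeletal regulator transcript Dnm3os, had 20274 ± 2148 CPM. Mir130a and Mir99b completed the 15 most abundant genes by mean CPM with 18612 ± 2544 and 16618 ± 2238 CPM (SD, n = 2 for every gene). In replicate 1 alone, genes that lay above Mir99b (15036 CPM) included Mir411 (16358 CPM) and Mir205 (15666 CPM). Mir30e, with 16415 ± 906 CPM (SD, n = 2), came directly after Mir99b by mean CPM and also lay above it in replicate 1.

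**Figure D1:**
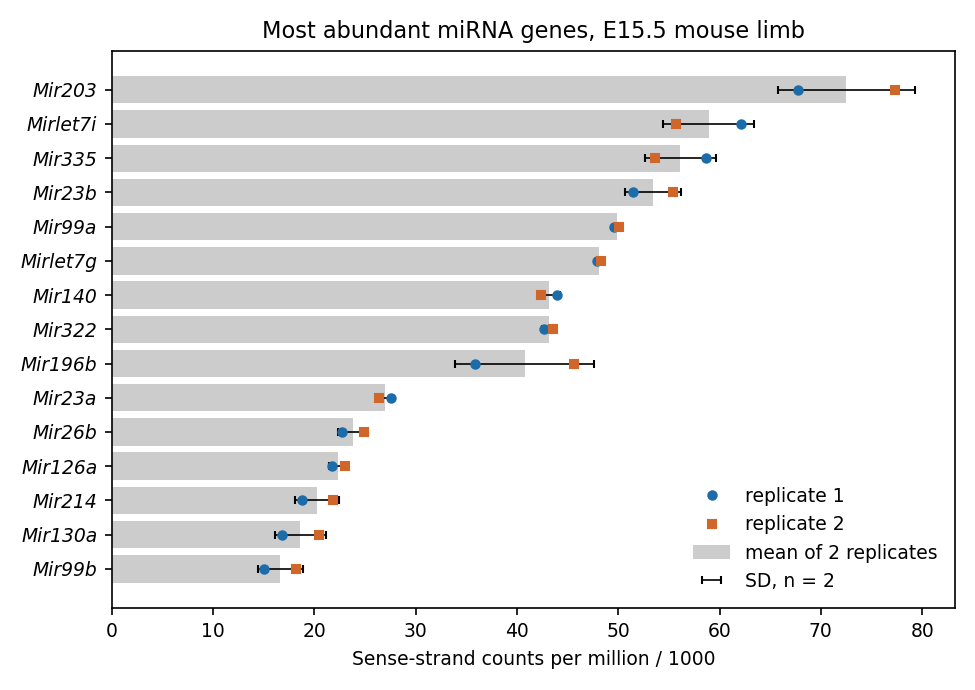
Sense-strand CPM, divided by 1000, of the 15 most abundant miRNA genes in embryonic day 15.5 limb, with bars for the mean, whiskers for the SD and points for each of the 2 replicates. Mir203 led with a mean of 72531 CPM, and Mir196b had an SD of 6885 CPM, the widest of the 15. Reads with several alignments are in no bar.

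Tissue by tissue, the epidermal, cartilage, Hox and mesenchymal miRNAs took large shares of the library, and the counted miRNAs of blood, nerve, liver and pluripotent cells took small ones. For nerve this leaves out reads common to gene copies, since 13 of the 16 listed genes share sequence with another precursor. The same holds for mesenchyme (6 of 11 genes), muscle (5 of 10) and let-7 (5 of 10), among other lists. Shares are of counted reads, and unequal capture of different miRNA sequences was not tested. The 15 lists together held 53.4% ± 0.870 of the sense counts (SD, n = 2). The let-7 family held 13.7% ± 0.649, the epithelial list 10.2% ± 0.859, and the miRNAs of the Dlk1-Dio3 imprinted region 9.01% ± 1.67. The Hox cluster miRNAs held 5.40% ± 0.712 and the cartilage miRNAs 4.67% ± 0.146. The muscle list held 0.830% ± 0.465, the widest spread between replicates relative to its mean.

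Of the 7 epithelial genes, all were detected. Beside Mir203, Mir205, a miRNA of basal and other stratified epithelia, had 16206 ± 763 CPM (SD, n = 2). Mir429, of the miR-200 family that represses Zeb1 and Zeb2, had 6596 ± 649 CPM. Without Mir203 in the counts, the epithelial share was 0.314 times its value. In the cartilage list of 3 genes, Mir140 was followed by Mir455, in an intron of the cartilage collagen gene Col27a1, with 3424 ± 348 CPM. Mir675, in an exon of the imprinted H19, had 98.9 ± 12.4 CPM. In the Hox list of 6 genes, Mir10b in the HoxD cluster had 8209 ± 81.5 CPM and Mir10a in the HoxB cluster 3339 ± 125 CPM.

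The mesenchymal list held 3.81% ± 0.103 of the counts, with 9 of 11 genes detected (SD, n = 2). Mir214 was followed by Mir143, a miRNA of smooth muscle and fibroblasts, with 9222 ± 1311 CPM, and by Mir21a with 6562 ± 78.6 CPM. The miR-17-92 list, linked to proliferation and to digit development, held 3.27% ± 0.294, with 14 of 15 genes detected. Mir17 had 13424 ± 1088 CPM, Mir93, overlapping an exon of the replication gene Mcm7, had 5502 ± 602 CPM, and Mir20a had 4057 ± 384 CPM. The endothelial list had 1 gene, Mir126a, with 2.23% ± 0.0903.

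In the Dlk1-Dio3 region of chromosome 12, whose miRNAs are expressed from the maternal allele, 44 of 50 genes were detected. Mir409, Mir376a, Mir299a and Mir380 are not among the 50, as they were not counted as genes of their own. Mir411, Mir127 and Mir487b led the region with 14652 ± 2413, 12306 ± 2611 and 11460 ± 2441 CPM (SD, n = 2). Mir411 and Mir487b each share at least 1 stretch of 20 bases with another precursor. In the let-7 family, with 10 of 10 genes detected, Mirlet7i and Mirlet7g were followed by Mirlet7d with 13099 ± 900 CPM. Mirlet7e and Mirlet7f-1 are not among the 10, as they were not counted as genes of their own. Of the 10 genes, 5 share sequence with another precursor and can rank too low.

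Skeletal muscle was represented mainly by Mir206, a muscle miRNA induced by MyoD, with 7919 ± 4429 CPM (SD, n = 2). Mir499, in an intron of the myosin gene Myh7b, had 168 ± 111 CPM, and Mir208b, in an intron of the slow myosin gene Myh7, had 118 ± 71.9 CPM. Mir1a-1, of the miR-1 family of striated muscle, had 1 count in each replicate, and Mir133a-1 had 0, which allows up to 0.704 and 0.582 CPM. Both share stretches of 20 bases with other copies of their families, so their true levels are not known from these counts.

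The remaining lists were each under 0.1% of the counts. Neurons and glia held 0.0846% ± 0.00956 (11 of 16 genes detected), with Mir128-1 at 190 ± 54.3, Mir132 at 168 ± 5.97 and Mir128-2 at 121 ± 36.7 CPM. Leukocytes held 0.0719% ± 0.00429 (4 of 5 genes), with the myeloid Mir223 at 433 ± 8.91, Mir155 at 196 ± 30.5 and Mir146 at 74.9 ± 0.825 CPM. Counted irrespective of strand, the leukocyte share was 1.95 times as large, with 3099 and 3821 antisense counts at Mir142b, which lies opposite Mir142. Neuroendocrine genes held 0.0662% ± 0.00660 (3 of 4), with Mir375, a miRNA of pancreatic islets, at 615 ± 61.5, Mir7-1 at 40.6 ± 6.0 and Mir7b at 4.70 ± 0.326 CPM. The erythroid Mir451a and Mir144 stood at 332 ± 9.92 and 85.0 ± 1.13 CPM, together 0.0417% ± 0.000878.

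Liver and gut genes held 0.0176% ± 0.00355 (4 of 5), with the hepatocyte miRNA Mir122 at 71.8 ± 20.3, Mir192 at 57.2 ± 9.64 and Mir194-2 at 39.2 ± 1.69 CPM. Pluripotency genes held 0.00279% ± 0.000132 (3 of 12), with Mir302a, Mir302d and Mir302b at 9.29 ± 0.788, 7.77 ± 1.37 and 3.49 ± 0.286 CPM (SD, n = 2 for all these values). Mir128-1, Mir128-2, Mir7-1, Mir146, Mir194-2, Mir302a and Mir302b share at least 1 stretch of 20 bases with other precursors, so these values leave out reads common to the copies.

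**Figure D2:**
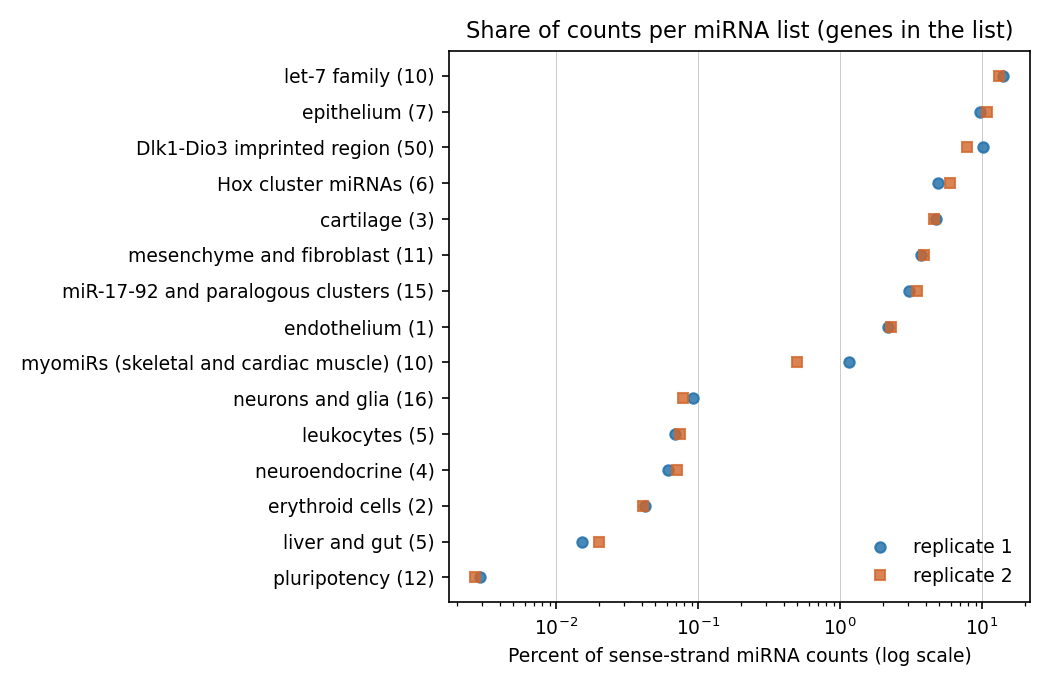
Share of sense-strand miRNA counts per list on a log scale, with 1 point per replicate and the number of listed genes in brackets. The replicates lie close together for most lists and apart for the muscle list, at 1.16% and 0.501%.

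The replicates ranked the miRNAs of the limb in nearly the same order, and differed most in muscle miRNAs. Mir206 was 2.31-fold lower in replicate 2, Mir499 was 2.74-fold lower and Mir208b 2.52-fold lower. The muscle list took 1.16% of the sense counts of replicate 1 (Wilson 95% interval 1.15 to 1.17) and 0.501% of replicate 2 (0.495 to 0.507). Of its 6 detected genes 6 were lower in replicate 2 and past the threshold, also when adjusted over the list alone. Their median log2 ratio of -1.27 lay below all 10000 random lists, whose 2.5 to 97.5 percentile range was -0.33 to 0.26.

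Across the 340 detected genes, Pearson's r was 0.996 and Spearman's rho 0.994, with genes that are not independent replicates. The log2 ratio had an SD of 0.345, and 309 genes (90.9%) were within 1.5-fold. The biological coefficient of variation was 14.7%. The counts of the 2 libraries differed by more than counting noise (chi-square of 57050 on 339 degrees of freedom). At this depth 173 genes passed an adjusted threshold of 0.05 in the exact binomial test, 86 higher and 87 lower in replicate 2. Of these, 8 differed over 2-fold.

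Lower in replicate 2 beyond 2-fold were Mir206, Mir133b, Mir499, Mir208a, Mir208b, Mir6240 and Mir1188, and higher was Mir215. Few counts lay behind Mir208a (34 in replicate 1 and 12 in replicate 2), Mir1188 (50 and 28), Mir6240 (54 and 31) and Mir215 (17 and 48). The log2 ratio of Mir499 was -1.46 (adjusted p = 1.09e-78, exact binomial test) and that of Mir208b -1.33 (adjusted p = 1.29e-47, exact binomial test). Mir133b, in the same cluster as Mir206, had -1.01 (adjusted p = 7.31e-16, exact binomial test), and Mir7689 had -0.94 (adjusted p = 6.53e-09, exact binomial test). In the other direction, Mir135b had a log2 ratio of 0.90 (adjusted p = 2.38e-20, exact binomial test) and the hepatocyte miRNA Mir122 had 0.58 (adjusted p = 8.56e-07, exact binomial test). Mir92-2, Mir452 and Mir598 followed with 0.45, 0.44 and 0.42, all past the threshold. Mir133b and Mir92-2 share sequence with other precursors, and reads common to both are in no count. With 2 libraries these tests describe the pools, and a difference in scaling between the libraries moves every gene.

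Beside muscle, the Dlk1-Dio3 miRNAs were lower in replicate 2 and the miR-17-92 miRNAs higher. Of 44 detected Dlk1-Dio3 genes 43 were lower, 39 of them past the threshold and 39 adjusted over the list alone. Their median log2 ratio was -0.37, below all 10000 random lists. Of 14 miR-17-92 genes 14 were higher, 8 past the threshold and 9 adjusted over the list alone, with a median of 0.24 at the 99.8 percentile. The 4 detected liver and gut genes were higher, 3 past the threshold and 3 adjusted over the list alone, with a median of 0.47 at the 99.6 percentile. That median fell inside the range when no count minimum was set, at the 96.3 percentile, and at the 97.3 percentile with at least 100 counts. In all, 4 of 13 lists lay outside the 2.5 to 97.5 percentile range. Random lists do not carry the joint transcription of clustered miRNAs, so these percentiles only describe the 2 libraries.

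The other lists stayed inside that range. All 7 epithelial genes were higher and past the threshold, also adjusted over the list alone, with a median of 0.11 at the 87.1 percentile. All 3 cartilage genes were lower and past the threshold in both adjustments, with a median of -0.21 at the 19.1 percentile. For the Hox list 4 of 6 genes were higher, the same number past the threshold in both adjustments, with a median of 0.15 at the 89.0 percentile, which became the 98.2 percentile with at least 100 counts. In the let-7 family 9 of 10 genes were lower and 5 of them past the threshold, 1 was higher and past it, and 6 passed adjusted over the list alone. The let-7 median was -0.11 at the 20.1 percentile. In the mesenchymal list 3 genes were higher and 3 lower past the threshold, 7 passed adjusted over the list alone, and the median was 0.02 at the 58.7 percentile.

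Leukocyte genes had a median of 0.18 at the 93.8 percentile with 1 gene past the threshold. For neuroendocrine genes the median was 0.20 at the 79.2 percentile, also with 1 gene. Neuronal genes had a median of -0.06 at the 38.5 percentile with 2 genes past it, both copies of Mir128. Pluripotency genes had 0.17 at the 60.6 percentile and none past it. In these 4 lists the counts adjusted over the list alone were the same. The endothelial Mir126a had a log2 ratio of 0.08 and passed the threshold in both adjustments. The median of the 2 erythroid genes was -0.02, with 0 past it in either.

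**Figure D3:**
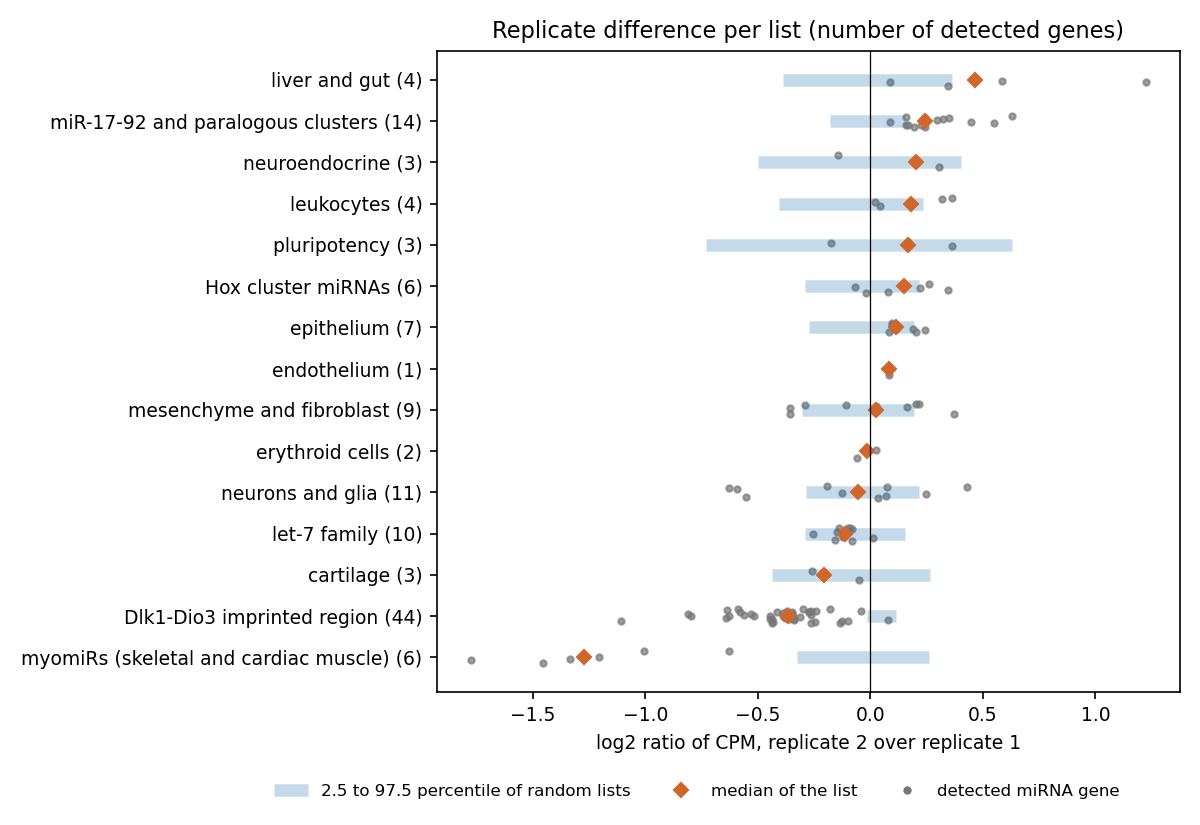
Log2 ratio of CPM, replicate 2 over replicate 1, of each detected miRNA gene (grey points) by list, with list medians (diamonds) and the 2.5 to 97.5 percentile range of medians of matched random lists (bars, lists of at least 3 genes). The muscle median of -1.27 and the Dlk1-Dio3 median of -0.37 lie left of their bars, and the medians of miR-17-92 (0.24) and of liver and gut (0.47) lie right of theirs.

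Reads on the antisense strand belonged to a few loci of the limb profile. Over all miRNA genes 3.35% ± 0.350 of the counts were antisense (SD, n = 2). The share was 3.60% in replicate 1 (Wilson 95% interval 3.58 to 3.61) and 3.10% in replicate 2 (3.09 to 3.12). Of 257 genes with at least 100 counts over both strands, 11 had over 50% antisense counts, and these held 99.9% of the antisense counts. Antisense counts alone were found at 7 of them, of which Gm25301, Gm24321, Gm25927, Gm25252 and Gm24083 had the most counts and Gm25750 and Mir142b fewer. Each of the 7 overlaps on the other strand a miRNA gene that had no row in the count tables used here.

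Gm25301 (ENSMUSG00000093026.1, chromosome 18, 61397813 to 61397925) lies opposite Mir378a, a miRNA from an intron of the metabolic coactivator gene Ppargc1b, and had 44683 and 38941 antisense counts. Gm24321 lies opposite Mir409 (31251 and 30866 antisense counts) and Gm25252 opposite Mir376a (19523 and 19295), both in the Dlk1-Dio3 region. Gm25927 lies opposite Mirlet7e (28077 and 36078), and Gm24083 opposite Mir191 (11179 and 13602). These counts are in none of the CPM values above, which use the sense strand.

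The leading genomic clusters of the limb combined members with very different counts. The 40 clusters with at least 2 detected genes held 143 detected genes and 49.8% ± 1.24 of the sense counts (SD, n = 2). The largest by its mean share was the Dlk1-Dio3 cluster led by Mir411, on chromosome 12 from 109709060 to 109747960, with 29 of 34 genes detected and 6.22% ± 1.1. It led in replicate 1 with 7.00%, while in replicate 2 its 5.44% was below the clusters of Mir23b (5.95%) and Mir322 (5.73%). The cluster led by Mir322, on chromosome X from 53047997 to 53054349, held 7 genes and 5.86% ± 0.184. Mir23b with Mir27b held 5.73% ± 0.302, and Mir99a with Mirlet7c-1 held 5.01% ± 0.0341.

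Within a cluster, the highest member exceeded the lowest detected member by a median of 14.9-fold, and by over 10-fold in 25 of the 40 clusters. This median was the highest of the distances tried. At 3 kb it was 11.4-fold, with 21 of 38 clusters over 10-fold, and at 50 kb 11.5-fold, with 26 of 45. In the Mir322 cluster the range was 1854-fold, down to Mir450-2 at 23.3 ± 1.60 CPM (SD, n = 2). In the Mir17 cluster it was 1549.7-fold, down to Mir19b-1 at 8.66 ± 2.30 CPM. Mir206 exceeded its neighbour Mir133b by 126-fold. The lowest member shared sequence with another precursor in 20 of the 40 clusters, and the highest in 8. Mir133b is among these lowest members. Such genes lose the reads that align to several copies, so these ranges can overstate differences in expression. Unequal capture of the different sequences within a cluster was not tested either.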

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

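The test within genomic clusters was chosen only after the levels of the cluster members had been seen, and the test over list members before its result was seen. Reads with several alignments drew attention because they carry signal that no gene count holds: they made up 29.4% of the reads of replicate 1 and 29.7% of replicate 2, and no control sample gives a level for them.

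A pattern that goes with them is the near absence of counts at some miRNA genes with several copies, such as Mir1a-1, Mir133a-1, Mir124a-1 and Mir9-2. Of the 30 list members under 10 counts in either replicate, 18 shared a stretch of 20 bases with another miRNA gene, against 32 of 127 other members (two-sided Fisher's exact test, p = 0.000426, odds ratio 4.45). Within clusters, the lowest member shared such a stretch in 20 of 40 clusters and the highest in 8 of 40 (two-sided exact McNemar test, p = 0.00183, with 13 clusters in which only the lowest did and 1 in which only the highest did). Both fit the loss of reads common to identical copies as an explanation of the low counts. Such reads entered no gene by the way they were counted, so an excess of this kind could be foreseen. Copies of a family share sequence with each other and are not independent, so the p-values are descriptive. The loss may lower the counts of multi-copy families in any list, and how far it does so is not known. The 12 low members without shared sequence stay outside this explanation. Mir142b is among them, with 0 sense counts but 3099 and 3821 antisense counts in replicates 1 and 2, opposite Mir142. No biological explanation was tested.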

How the results depend on the processing

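Here 3 settings were chosen only after the result was seen, namely the antisense share without genes opposite another miRNA gene, the GC correction and library totals without the muscle list. With counts irrespective of strand the 10 most abundant genes took 47.6% and the lists together 51.9%, as the antisense counts enlarge the total. For the lists, counts opposite Mirlet7e, Mir409 and Mir376a enter that total under Gm genes that are in no list. With Mir203 left out of both the shares and the total, the lists took 49.7%. The rest of the 10 genes then took 45.3%, with no gene put in the place of Mir203. Detected genes numbered 559 at 1 count in both replicates. Pearson's r was 0.994 with at least 100 counts and 0.997 with a pseudocount of 10, which also lowered the SD of the log2 ratio to 0.268. Without a minimum Spearman's rho was 0.927 and the SD 0.434, and the muscle median was -1.004, with members of 0 to 4 counts included. The antisense share was 0.00211% without genes opposite another miRNA gene, which by construction leaves out their counts. Genes past the threshold between replicates numbered 162 to 184 over 7 settings, with 162 to 172 of them among the 173, and 76 higher against 91 lower with DESeq2 size factors. The 10 genes named for their ratio kept direction and side of the threshold in those settings. Without replicate 1, the levels of Mir206, Mir499 and Mir208b were 0.605, 0.534 and 0.568 times the mean, and the muscle share 0.603 times. Muscle, Dlk1-Dio3 and miR-17-92 stayed outside the range of random lists in all settings tried. No pluripotency gene was left at 100 counts. With counts irrespective of strand, 11 of 49 named CPM values and 4 of 15 list shares moved by more than the replicate SD, and without Mir203 in the total 22 and 8 did. With 2 replicates, leaving 1 out moves a mean by less than its SD by construction, so that setting says nothing about the stability of a level. Depth limits genes near 10 counts, and 2 libraries give no test of a biological difference.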

Other observations

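The tests of opposite genes, strand, scaling and muscle share were chosen only after the result was seen, as were the GC correction and the summaries by chromosome and gene context. Chromosome 12, with Mir203 and the Dlk1-Dio3 region, held 16.6% ± 0.997 of the sense counts over 52 detected genes (SD, n = 2). Chromosome 6, with Mir335 and Mir196b, held 11.1% ± 0.413 over 12 detected genes, and chromosome X 8.71% ± 0.287 over 38. By gene context, 147 detected miRNA genes in introns held 39.4% ± 0.733, 81 in exons 31.4% ± 0.0413, and 112 without another gene on their strand 29.1% ± 0.774.

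The 11 genes with over 50% antisense counts, which hold 99.9% of such counts, all overlap on the other strand a miRNA gene with no row in the count tables used here, against 9 of 246 other genes (two-sided Fisher's exact test, p = 2.58e-14). The tables argue against a loss of strand in the library, since the highest antisense share among the other genes was 0.225%. That highest share replaced the median share as the deciding value after both had been seen. The antisense counts may therefore be reads of Mir378a, Mirlet7e, Mir191, Mir142 and others, which would place the Mir378a locus at rank 26 when strands are combined. No biological explanation was tested.

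Scaling did not move the lower muscle miRNAs of replicate 2. Their median log2 ratio was -1.28 at the nearer to 0 of TMM and DESeq2 factors. These factors differed from the library totals by only 0.005 and 0.021 on the log2 scale, too little to bring the list near 0. A correction for precursor GC content also left -1.28. Its fit was weak (r = -0.136), and a bias tied to the mature sequences was not tested. A smaller share of muscle in the second pool is a hypothesis that cannot be told apart from other differences between the pools, since each pool is 1 library. All 6 detected members were lower, yet the lowest median among cartilage, epithelium and mesenchyme was also below 0, at -0.21 for cartilage, where random lists had an SD of 0.193. An allowance for that SD was added after the cartilage median was seen to lie just past the fixed bound first set, which alone would have counted against the hypothesis. Differences in stage or dissection between the pools stay open and untested. The Dlk1-Dio3 miRNAs were also lower in replicate 2, and 2 libraries cannot show whether this is linked to muscle.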
